A study of Mus musculus with 2 samples.

How the data were processed

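H3K27me3, the trimethylation of lysine 27 of histone H3 laid down by Polycomb repressive complexes, was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in lung of newborn mice (postnatal day 0). The labels describe 1 group with 2 biological replicates, each a pool of healthy animals of both sexes, of the strain given as B6NTac;B6NCrl/Lap. Replicate 1 was lung from 15 mice and its 2 technical replicates were handled together, and replicate 2 was lung from pooled mice whose number the labels do not give. The labels name Illumina HiSeq instruments for replicate 1 and none for replicate 2. A control experiment is named in the labels and was not analysed here.

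Peak lists were deposited for each replicate on its own, for both replicates pooled, and for a replicated set. Per the file headers in the accompanying text, all are narrowPeak lists on mm10, and the replicated set was derived by the authors from the pooled peaks and the peaks of both replicates. The aligner, the peak caller, their versions and the thresholds are not given in the sources used here. The deposited files give a fold enrichment for each peak, a ratio that was read as signal over control, as is usual for this format. They also hold the −log10 p-value and the −log10 q-value of each peak, as the authors' peak caller wrote them. These values were used only to describe, rank or filter peaks within a list. The files hold no read counts, so the depth of each library is unknown and no value could be weighted by it. Every peak lay on chromosomes 1 to 19 or X.

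Genes and coordinates came from the GENCODE M21 annotation and the GRCm38 (mm10) assembly, the build of the files, and positions are given counting from 1. The 21728 protein-coding genes on these chromosomes were used, with the longest record kept where a symbol occurred more than once. The transcription start site (TSS) was the annotated 5′ end of the gene, and a promoter was the window of 1 kb on each side of it. A promoter was called occupied when at least 1 bp lay under a peak. The fold at a promoter is the highest among the peaks that meet its window. The covered share is the percentage of that window under peaks. For the replicated set these are pooled peaks, so the share is not that of bases covered in both replicates.

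Overlap between replicates was the share of peaks of one replicate that met a peak of the other by at least 1 bp, together with the Jaccard index over base pairs. The same values were computed after 100 random placements of the peaks of replicate 2 on their own chromosome outside assembly gaps. The distribution over promoters, exons, introns and intergenic sequence was set against 100 such placements of the peaks tested, where the smallest two-sided p is 0.0198. The number of occupied promoters in each of 23 gene lists was compared with all other protein-coding genes by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over the 23 lists and a threshold of 0.05. The lists held Hox cluster genes, transcription factors of neural, gut, liver, pancreas, heart, muscle, kidney, gonad and lung lineages, markers of lung and other cell types, signalling ligands and antagonists, polycomb subunits, cell cycle inhibitors, imprinted genes, ribosomal protein genes, constitutively used genes, olfactory receptors and keratins. All members matched the annotation. The airway list and the keratins shared 2 genes, Krt5 and Krt15, and the imprinted genes and the cyclin-dependent kinase inhibitors shared Cdkn1c. Hox genes of paralogue groups 1 to 8 were compared with groups 9 to 13 by the covered share, with a two-sided permutation test over genes (100000 resamples, smallest possible p 1e-05). Replicated peaks within 3 kb of each other were joined into domains, which were ranked by the base pairs under peaks. Shares carry 95% Wilson intervals, which cover counting error only. The p-values over genes or placements describe these libraries. With 2 replicates and no second condition, no test across animals was possible, and genes of one cluster or list are not independent replicates.

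The groups, lists, tests and most alternatives were fixed before the data were examined. Genes were named by a rule fixed at the same time. In each list these were up to 3 occupied members with the most base pairs under replicated peaks within 5 kb of the TSS and up to 3 unoccupied members in list order. To these were added the 10 genes with the highest fold enrichment at an occupied promoter, the 10 domains with the most base pairs under peaks, and for each replicate the 5 genes with the highest fold among promoters with a peak in that replicate alone and none in the replicated set. Genes named below outside the rule are marked as such.

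The alternatives were peaks with q of 0.01 or less or fold of 3 or more, each replicate's peaks alone, the pooled peaks, the bases covered in both replicates, overlap of at least 50%, the 10000 highest-ranked peaks, promoter windows of 2 and 5 kb, a minimum of 500 bp, any transcript start, joining distances of 1 and 10 kb, 10000 random lists matched on promoter CpG content in 20 bins, and 1000 rotations of the peaks along their chromosomes. Autosomes alone, 1000 shifts of the occupied state along the genes in genome order, the mean over all transcript starts of each Hox gene and Hox clusters A and B alone were added after the data were seen. The procedures were tested on simulated data. All 2060 planted promoters were recovered, all 4 of the lists planted at the lowest occupancy were called, 0 of 40 unplanted lists were called, and a planted overlap of 40% was read as 41.1%. The planted peaks lay on the TSS, so their recovery was fixed by construction. The peaks planted as shared were exact copies, so their overlap was fixed as well, and partial overlap was not simulated. The unplanted lists were genes drawn at random, so false calls in lists of neighbouring genes were not tested. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.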

Results

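H3K27me3 was profiled by ChIP-seq in lung of mice on the day of birth, in 2 biological replicates of 1 group, each a pool of lungs from animals of both sexes. The mark is deposited by Polycomb repressive complex 2 and is found at silenced developmental genes. The labels name no treatment and no second tissue, so the comparisons available were those between the replicates and those between genes or regions within the tissue. The authors listed 36102 peaks in replicate 1, 36350 in replicate 2 (36226 ± 175, SD, n = 2), 35091 in the pooled data and 11667 in the replicated set. The median fold enrichment given by the authors was 3.36 in replicate 1, 3.20 in replicate 2 and 3.69 in the replicated set. Read depth is unknown, since the files hold peaks and no counts.

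Regulators of other organs carried the mark at birth. All 35 neural transcription factors had a replicated peak within 1 kb of the TSS, against 10.1% of all other protein-coding genes (Fisher's exact test, adjusted p = 1.95e-34). Among them, Pax7, a paired-box factor of the dorsal neural tube and muscle stem cells (chromosome 4, gene from 139737062 to 139833528, TSS 139833528), had 97.5% of its promoter window under replicated peaks, 90.0% in replicate 1 and 87.9% in replicate 2. The covered share was 91.8% at Olig2, a factor of oligodendrocyte and motor neuron progenitors, and 97.7% at Emx2, a factor of the developing cortex. Genes of mature neurons were marked as well, with 14 of 18 neuronal effector genes occupied (Fisher adjusted p = 1.03e-10). Gad2, which makes GABA, and Nefl, a neurofilament subunit, had windows covered over 100% of their length, and Slc32a1, the vesicular GABA transporter, over 91.3%. The neuronal genes Gad1, Syn1 and Elavl4 had no replicated peak in the window. Syn1, on the X chromosome, had a peak there in replicate 1 alone (32.1% covered) and Elavl4 in replicate 2 alone (12.4%). On X replicate 1 had far more peaks than replicate 2, as described below.

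Transcription factors of gut, liver and pancreas were occupied in 14 of 20 cases (Fisher adjusted p = 9.18e-10). Onecut1 and the intestinal factor Cdx2 were covered over 100% of the window and the stomach factor Barx1 over 98.2%, whereas the hepatic nuclear factors Hnf1a, Hnf4a and Hnf4g had no replicated peak there. Factors of heart, skeletal muscle, kidney and gonad were occupied in 20 of 25 cases (Fisher adjusted p = 2.11e-15). The kidney factors Pax2 and Wt1 were covered over 100% and Lhx1 over 89.6%. The unoccupied members included Myf5, Myf6 and Myog, 3 of the muscle-determining factors. Secreted ligands and antagonists of the WNT, FGF, BMP and hedgehog pathways were occupied in 36 of 43 cases (Fisher adjusted p = 2.05e-28). Gdf7, Wnt10a and Wnt10b were covered over 100% of the window, while Wnt8b, Fgf1 and Fgf4 were unoccupied.

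Regulators used in the lung itself were also occupied more often than other genes. The number of occupied genes was not tested against that of the lists of other organs. Replicated peaks lay at 10 of 22 lung epithelial transcription factors (Fisher adjusted p = 6.34e-05), with 13 of 22 occupied in replicate 1 and 9 of 22 in replicate 2. Sox2, a factor of the proximal airway (chromosome 3, gene from 34650405 to 34652461), was covered over 100% of the window, Irx1 over 84.1% and Foxa1 over 40.1%. At Foxa1 the share was 75.8% in replicate 1 and 15.3% in replicate 2. Sox9, Id2 and Etv5, which are used in the distal tip epithelium of the developing lung, had no peak within 1 kb of the TSS in the replicated set or in either replicate. Within 5 kb Sox9 had 1235 bp under replicated peaks. Nkx2-1, the factor that specifies lung epithelium, was singled out after its values were seen. Its promoter on chromosome 12 (TSS 56536908) was covered over 54.5% in the replicated set, 35.2% in replicate 1 and 43.9% in replicate 2. Among lung mesenchymal factors and signals 11 of 23 were occupied (Fisher adjusted p = 1.5e-05), with 17 in replicate 1 and 12 in replicate 2. This count depended on the setting, as the occupied share rose from 47.8% to 73.9% with the peaks of replicate 1 or a window of 2 kb and to 78.3% with the pooled peaks, and fell to 43.5% at fold of 3 or more, 39.1% with the bases covered in both replicates and 34.8% with at least 500 bp covered. Twist1 was covered over 100%, Pdgfra, a receptor of alveolar fibroblast progenitors, over 82.0%, and the hedgehog effector Gli2 over 66.4%. At Pdgfra the share was 81.8% in replicate 1 and 33.5% in replicate 2. Tbx2, Tbx3 and Gli1 had no replicated peak in the window. Gli1 did have a peak there in each replicate, over 29.5% of the window in replicate 1 and 13.3% in replicate 2. Tbx2 had one in the pooled peaks.

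Markers of differentiated lung cells were occupied at rates that did not pass the test, apart from those of endothelium. Among 16 alveolar epithelial markers 3 were occupied (Fisher adjusted p = 0.298). These were Aqp5 and Pdpn, both used in flat type I cells, covered over 52.8% and 17.6%, and Abca3, the lipid transporter of type II cells, covered over 18.8%. The surfactant genes Sftpa1, Sftpb and Sftpc had no replicated peak, and Sftpc had a peak in replicate 2 alone. Airway markers were occupied in 2 of 16 cases (Fisher adjusted p = 0.675), namely Ascl1 (100%) and Calca (28.3%), both genes of neuroendocrine cells, while the secretory genes Scgb1a1, Scgb3a1 and Scgb3a2 were unoccupied. Endothelial markers were occupied in 8 of 20 cases (Fisher adjusted p = 0.0011). The VEGF receptor Flt1 was covered over 87.0% of the window, Sox18 over 97.3% and Tal1 over 63.4%, while Pecam1, Cdh5 and Tek were unoccupied. Fibroblast and smooth muscle markers were occupied in 4 of 17 cases (Fisher adjusted p = 0.145), among them Des (65.2%), Cnn1 (46.8%) and Col1a1 (35.1%), and Col1a2, Col3a1 and Eln were not. At Col1a1 the fold was 2.28 and the −log10 q 1.22, with 10.1% covered in replicate 1 and 13.5% in replicate 2. The list had 3 occupied genes at q of 0.01 or less and 2 at fold of 3 or more. With the peaks of replicate 1 alone that list was occupied in 6 of 17 cases and passed the test (Fisher adjusted p = 0.0384). Over the alternatives the adjusted p reached 0.674 by Fisher's test at fold of 3 or more. The lowest was 0.00328 under rotations of the peaks, a permutation test against the whole genome and not against other genes. Immune markers were occupied in 3 of 18 cases (Fisher adjusted p = 0.461), which were the lymphoid factors Pax5 and Ikzf1 and the complement gene C1qa. Ptprc, Cd68 and Lyz2 were unoccupied.

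Hepatocyte and germ cell lists had no occupied members. None of 16 hepatocyte markers, including Alb, Apoa1 and Apoa2, and none of 16 germ cell genes, including Ddx4, Dazl and Dppa3, had a replicated peak at the promoter (Fisher adjusted p = 0.458 for each list). Random lists matched on CpG content held 0.578 and 1.75 occupied genes on average, so these counts of 0 carry little weight, and no expression was measured here. With the peaks of replicate 2 alone 1 gene of each list was occupied. Olfactory receptor genes, which are used in the nose, were the 1 list occupied less often than other genes, with 0 of 1134 against 10.8% (Fisher adjusted p = 8.46e-54). Their promoters are poor in CpG, and random lists matched on CpG content held 8.40 occupied genes on average (permutation test, adjusted p = 0.00092). The peaks of replicate 1 lay at 6 of these promoters and those of replicate 2 at 8. Among 49 keratins 2 were occupied, Krt87 and Krt8 (Fisher adjusted p = 0.298), with 4 in replicate 1 and 7 in replicate 2. Among 16 striated muscle markers 3 were, Acta1, Ckm and Ryr2, while Myh6, Myh7 and Tnnt2 were not (18.8%, Fisher adjusted p = 0.298). With the peaks of replicate 2 alone 5 of the 16 were occupied (31.2%, Fisher adjusted p = 0.0799). The list passed Fisher's test in no setting, and its adjusted p was 0.9 by that test with the pooled peaks. Under rotations of the peaks, a permutation test against the whole genome and not against other genes, it was 0.00328.

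Of genes used in all cells, 0 of 30 constitutively used genes such as Actb, Gapdh and Ppia were occupied (Fisher adjusted p = 0.12), and 1 of 60 ribosomal protein genes was (Fisher adjusted p = 0.0556). That gene was Rpl3, whose annotated start on chromosome 15 (80091868) lies 534 bp from the TSS of the synaptic gene Syngr1, a neighbour looked up after the peak was seen. Both lists passed as less often occupied in a permutation test against random lists matched on CpG content (adjusted p = 0.0046 for ribosomal proteins and 0.0322 for the constitutively used genes), and with shifts along the genes, also a permutation, the adjusted p = 0.0383 and 0.138. Of 27 polycomb subunit genes 1 was occupied, Cbx8 (Fisher adjusted p = 0.541), and Ezh1, Ezh2 and Eed were free, with 2 of 27 occupied in each replicate. Among 7 cyclin-dependent kinase inhibitors the neighbours Cdkn2a (100% covered) and Cdkn2b (36.0%) were occupied and Cdkn1a, Cdkn1b and Cdkn1c were not (Fisher adjusted p = 0.238). With a window of 5 kb 4 of the 7 were occupied and the list passed the test (Fisher adjusted p = 0.0128). That was the lowest adjusted p over the alternatives, and the highest was 0.478 with shifts along the genes, a permutation test. Imprinted genes were occupied in 8 of 23 cases (Fisher adjusted p = 0.00295). Ascl2 was covered over 100%, Igf2 over 35.3% and Gnas over 10.4%, and Igf2r, Cdkn1c and Slc22a18 were unoccupied. Of all 21728 protein-coding promoters 2221 were occupied (10.2%, 95% Wilson interval 9.83 to 10.6%), and of the 23 lists 10 were occupied more often, 1 less often and 12 without a call.

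**Figure D1:**
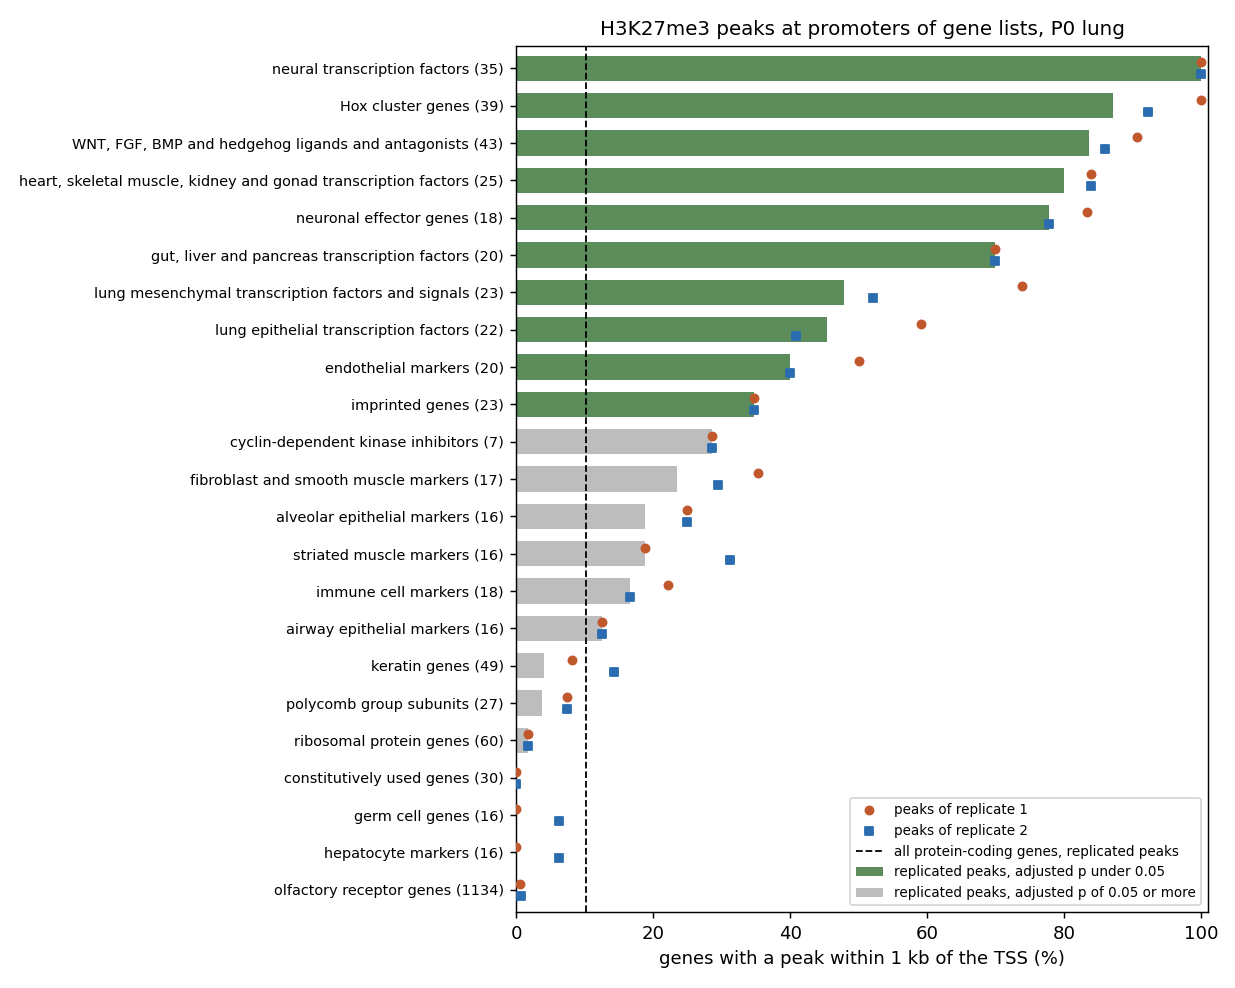
Percentage of genes in each list (number of genes in parentheses) with a peak within 1 kb of the TSS; bars are the replicated set, points each replicate, and the dashed line is all protein-coding genes at 10.2%. Neural transcription factors reach 100%, the lung lists 45.5% and 47.8%, and olfactory receptors, which passed the test, 0%.

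The highest fold enrichment at an occupied promoter was 8.64 at Pcdh8, a protocadherin gene (chromosome 14, TSS 79771312). It was followed by Gbx2, a factor of the midbrain-hindbrain boundary, at 8.12, and by Celsr3, Hmx1, Tfap2c and Uncx, each at 7.95. Adra2c, Camk2b, Grid1 and Hs3st3b1 stood at 7.78 each, a value shared with Lhx1, Neurog2, Pax7 and Ptf1a, so that the 10 end within a tie cut by alphabetical order. Neurog2 and Ptf1a are named for this tie, outside the rule. All of these folds are values of the pooled peaks as the authors gave them, and all 10 promoters also had a peak in each replicate.

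Most genes of the Hox clusters, which specify position along the body axis, carried the mark at the promoter. In clusters A and B the genes of groups 9 to 13, at the 5′ end, were covered more fully than those of groups 1 to 8. Of 39 Hox genes 34 had an occupied promoter (Fisher adjusted p = 3.32e-28), including all 9 of cluster C and all 9 of cluster D, 8 of 11 of cluster A and 8 of 10 of cluster B. Hoxc12, Hoxa10 and Hoxd10 had 100%, 100% and 97.5% of the window under replicated peaks. The 5 unoccupied genes were Hoxa2, Hoxa4, Hoxa5, Hoxb3 and Hoxb4, all of groups 2 to 5, of which Hoxa5 is needed for normal lung development. Hoxb3 and Hoxb4 were named after their values were seen. Replicate 1 had a peak at each of the 5 promoters, and at Hoxa5 it covered 69.8% of the window, while replicate 2 had none at Hoxa2 and Hoxa5. The covered share was 94.4% ± 6.41 (SD, n = 16 genes) for groups 9 to 13 and 59.97% ± 38.7 (SD, n = 23 genes) for groups 1 to 8, a difference of 34.4 percentage points (permutation test, two-sided, p = 0.00084). In clusters A and B alone it was 50.1 points, from 42.5% ± 37.4 (SD, n = 15 genes) to 92.6% ± 8.77 (SD, n = 6 genes; exact permutation test, two-sided, p = 0.00499), while the means over all genes of clusters C and D were 95.6% and 92.8%. Over the 4 clusters the difference was 26.97 points with the peaks of replicate 1 and 29.3 with those of replicate 2. With the bases covered in both replicates the means were 66.3% for groups 9 to 13 and 35.6% for groups 1 to 8. Neighbouring Hox genes are not independent, and some annotated starts lie inside a neighbour, as at Hoxc5 (TSS 102967443), which begins beside Hoxc10 (TSS 102966796).

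**Figure D2:**
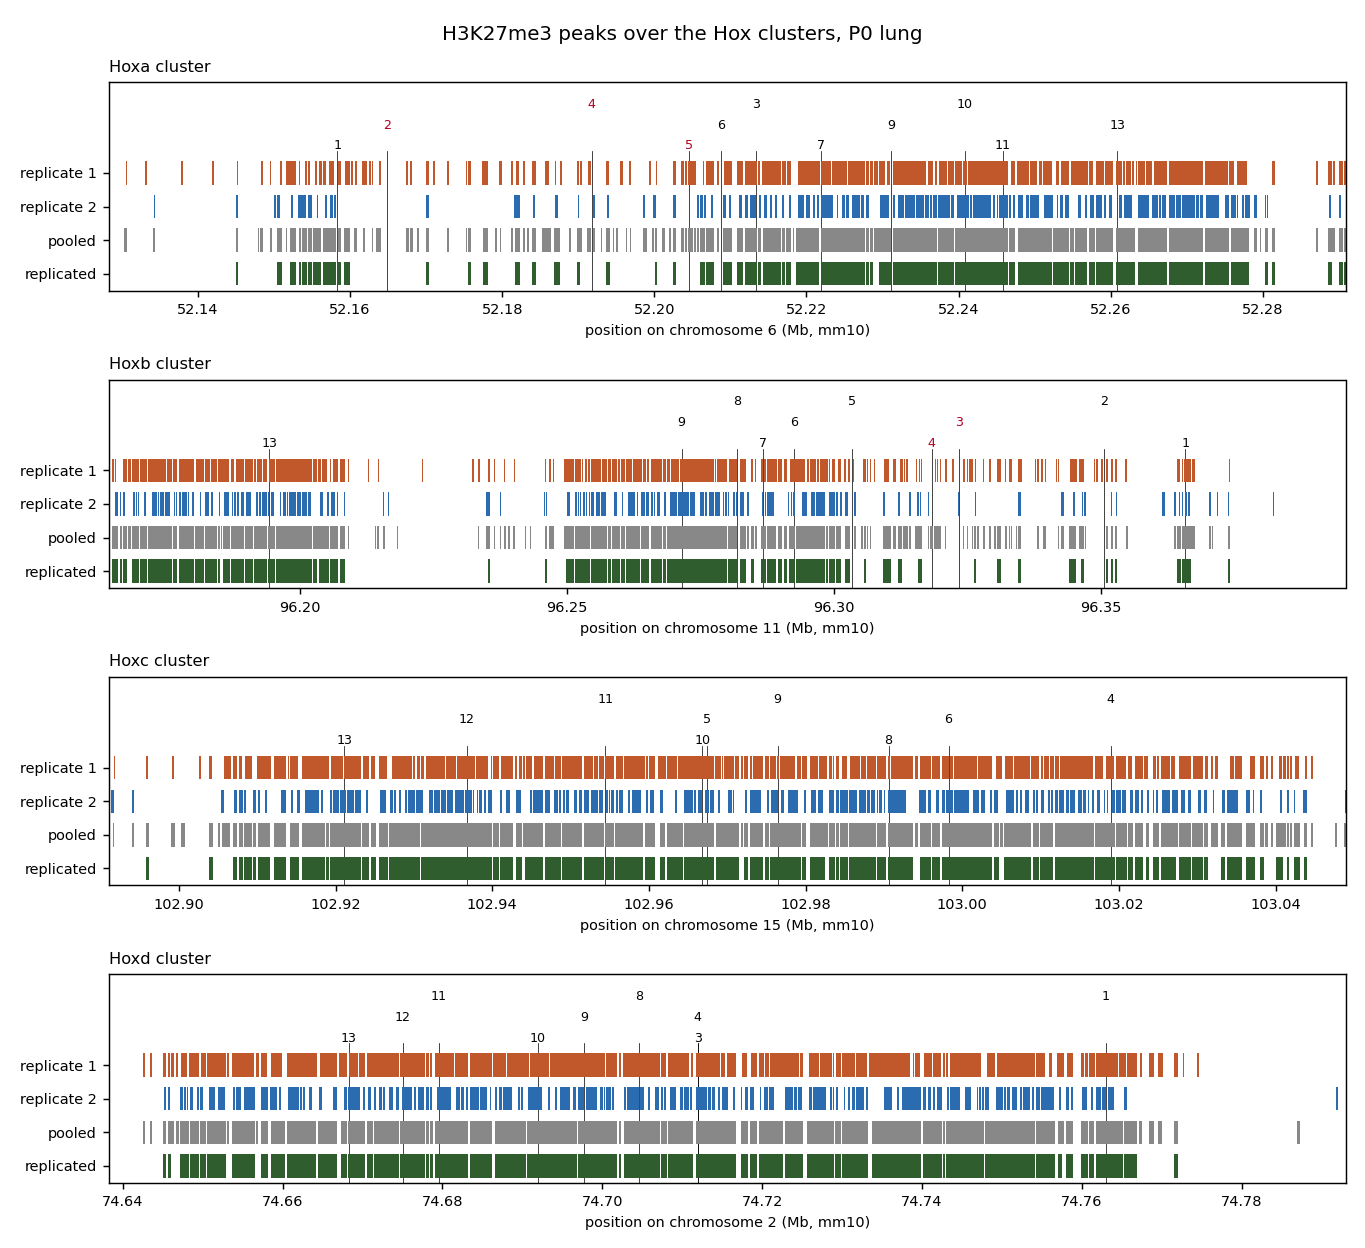
Peaks over the 4 Hox clusters in each replicate, in the pooled data and in the replicated set, by position in Mb on mm10; vertical lines and numbers mark the annotated TSS and paralogue number of each gene, in red for the 5 genes without a replicated peak within 1 kb. Every annotated TSS of clusters C and D has a replicated peak within 1 kb, and clusters A and B have gaps, among them those at the 5 genes in red and one between Hoxb13 and Hoxb9.

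The 10 broadest domains each held the TSS of at least 1 developmental regulator, and 5 of them lay over a Hox cluster or part of it. Joining replicated peaks gave 4499 domains, of which 177 held at least 10 kb under peaks, and these 177 made up 31.5% of the covered length. A protein-coding TSS lay in 155 of the 177. The domain with the most base pairs under peaks spanned Hoxc13 to Hoxc4 (chromosome 15, 102903858 to 103044044) with 115.9 kb under peaks, 109.9 kb in replicate 1 and 73.8 kb in replicate 2. The next spanned Evx2 and the Hoxd genes (chromosome 2, 74645074 to 74766917, 107.8 kb), the Hoxa genes from Hoxa6 to Hoxa13 (chromosome 6, 52205940 to 52281674, 65.2 kb) and Hoxb9 to Hoxb5 (chromosome 11, 96249823 to 96305938, 46.1 kb). Below them stood Zic1 and Zic4, regulators of the dorsal neural tube, with 43.9 kb, Hoxb13 with 38.3 kb and Tfap2a, a neural crest and ectoderm factor, with 37.5 kb. Pax3, the heart and gut factor Gata4 and the heart and limb factor Hand2 completed the 10 domains with 35.8, 35.0 and 34.7 kb. In each of the 10 domains replicate 1 covered more base pairs than replicate 2.

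Across the genome, replicated peaks were concentrated at promoters. They covered 10.8 Mb, and 22.1% of this length lay within 1 kb of a protein-coding TSS, against 1.73% after random placement, a ratio of 12.8. Exons outside promoters held 3.47 times the random length, introns 0.807 times and intergenic sequence 0.613 times (two-sided permutation of peak positions, p = 0.0198 for each, the smallest that 100 placements can give). The promoter ratio was 10.01 for the peaks of replicate 1 and 9.17 for those of replicate 2. With promoters of 5 kb on each side the ratios were 7.01 for promoters, 1.83 for exons, 0.412 for introns and 0.420 for intergenic sequence.

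The replicates shared part of their peaks, and the shared ones had a higher median fold and were wider. Of the peaks of replicate 1, 34.4% (95% Wilson interval 34.0 to 34.9%) met a peak of replicate 2, against 1.06% after random placement. Of the peaks of replicate 2, 40.3% (39.8 to 40.8%) met a peak of replicate 1, against 0.977%. The Jaccard index was 0.232, against 0.00266. Shared peaks of replicate 1 had a median fold of 3.87 and a width of 446 bp, and those found in it alone 3.26 and 231 bp. In replicate 2 the values were 3.52 and 313 bp against 3.13 and 208 bp. Among the tenth of peaks with the highest fold, 87.7% of replicate 1 and 86.6% of replicate 2 were shared. A q of 0.01 or less was reached by 51.7% of peaks in replicate 1 and 14.5% in replicate 2. With that threshold the shared percentage became 21.8% for replicate 1 and 78.7% for replicate 2. The replicated set was a subset of the pooled peaks (33.2% of them), and 96.5% of it met a peak of replicate 1, 86.4% a peak of replicate 2 and 83.1% both.

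At promoters, 2243 genes had a peak in both replicates, 800 in replicate 1 alone and 607 in replicate 2 alone. Among promoters found in replicate 1 alone and absent from the replicated set, the highest folds were at the neuronal gene Astn1 (5.92), Gpr45 (5.33), and Cds1, Cited1 (on the X chromosome) and Ptgdr (5.03 each). In replicate 2 alone they were at Cygb (4.70), Cpn2 (4.49), Elovl7 (4.39), Efemp1 (4.17) and Fam135b (4.17). The covered share at these 5 genes ranged from 10.9% at Cpn2 to 28.5% at Efemp1 in replicate 2. With 2 replicates, a promoter found in one of them alone cannot be told from one near the threshold.

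The X chromosome set the replicates apart. Replicate 1 had 2789 peaks on X and replicate 2 had 378, a ratio of 7.38, whereas the ratio on the 19 autosomes ran from 0.826 to 1.02. By density, X had 16.3 peaks per Mb in replicate 1, within the autosomal range of that replicate (7.40 to 23.4). In replicate 2 it had 2.21, below every autosome (8.82 to 23.2). In replicate 1, 5.16% of the peaks on X lay at a promoter, against 17.0% of its autosomal peaks. The order was the same in replicate 2 (9.52% against 14.2%), the pooled peaks (8.55% against 16.9%) and the replicated set (15.8% against 27.7%). The replicated set held 158 peaks on X, and 23 of its 2221 occupied promoters lay there. Of the 800 promoters occupied in replicate 1 alone 69 were on X, and of the 607 occupied in replicate 2 alone 8 were.

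**Figure D3:**
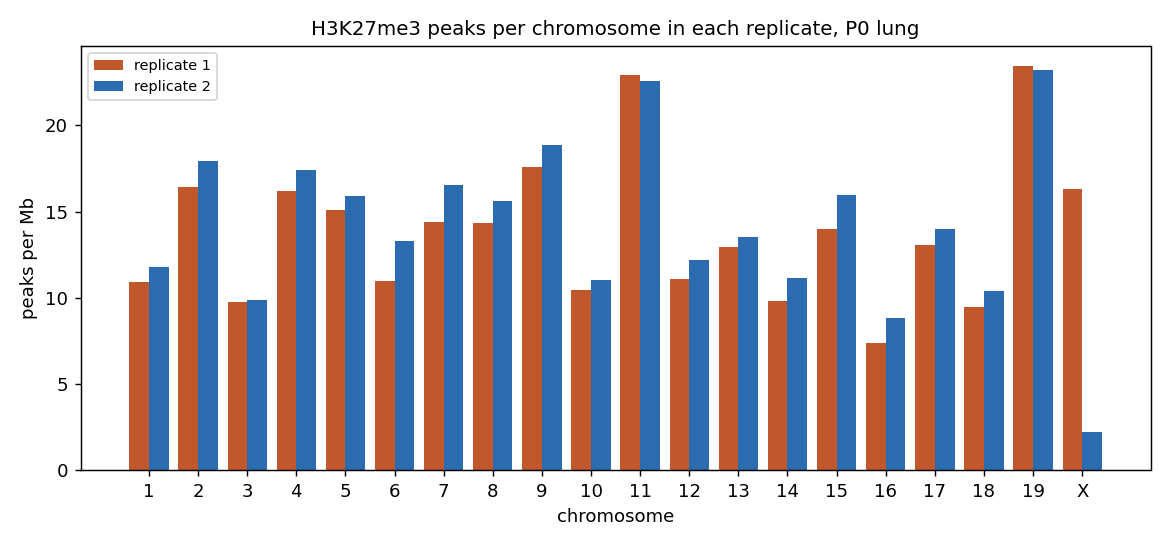
Peaks per Mb on each chromosome in replicate 1 and replicate 2. On X the values are 16.3 and 2.21 peaks per Mb, while on each autosome the replicates lie close together, with ratios from 0.826 to 1.02. The autosomes run from 7.40 to 23.4 peaks per Mb in replicate 1 and from 8.82 to 23.2 in replicate 2.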

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

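The autosomes-only setting, the shifts along the genes, the mean over transcript starts and the restriction to Hox clusters A and B were chosen only after the data were seen. No paired analysis was possible because the design holds a single group. The promoter ratio and the Hox difference kept their direction and stayed under the threshold of 0.05 in every alternative run for them, though the promoter ratio of 12.8 fell to 7.01 with windows of 5 kb, and 7 to 9 of the 10 broadest domains were again among the 10 broadest. Of the values for the planned comparisons 60 stayed and 26 moved, with the settings added later included. A count stayed when it kept within a fixed ratio of the main value, and an overlap when it kept within the main Wilson interval. The 2 rules are unlike. The 2850 occupied promoters without replicate 1, in place of 2221, counted as stayed, and an overlap of 35.3% in place of 34.4% as moved. The cause of these moves was not tested, except that a stricter overlap or threshold leaves fewer peaks by construction. The overlap of replicate 1 with replicate 2, 34.4%, became 21.8% at q of 0.01 or less, 35.3% at fold of 3 or more, 21.5% with 50% of the peak, 13.7% with a reciprocal 50%, 45.6% among the 10000 highest-ranked peaks and 37.0% on autosomes. For replicate 2, 40.3% became 78.7, 45.6, 33.5, 13.6 and 54.3% under the same settings from q to rank. With 50% of the peak required, replicate 1 met 87.0% and replicate 2 60.1% of the replicated peaks. In place of the 11667 replicated peaks, leaving out a replicate gave 36102 to 36350 peaks, and pooling gave 35091.

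The 10 lists occupied more often became 11 without replicate 2, 11 with windows of 5 kb, where the cyclin-dependent kinase inhibitors passed, and 16 under rotations of the peaks, which compare genes with the whole genome and not with other genes. The 1 list occupied less often became 3 without replicate 1, 3 without replicate 2, 3 with the pooled peaks, 3 against CpG-matched lists, and 2 on autosomes, with windows of 2 or 5 kb, with any transcript start or under shifts. Single lists passed the threshold newly in 21 cases and turned direction in 11, in each of these without a call in either setting. The turns were airway markers at 12.5% in replicate 1, in replicate 2, in the pooled peaks and at 5 kb, keratins at 14.3% in replicate 2 (8.16% in replicate 1, not turned) and 4.08% under rotations, polycomb subunits at 14.8% with 2 kb, 18.5% with 5 kb and 3.70% under rotations, alveolar markers at 6.25% with 500 bp, and ribosomal proteins at 1.67% under rotations. Depth is unknown, so whether deeper libraries would raise the overlap cannot be read from these files.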

Other observations

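The grouping of genes by symbol, the tests on the X chromosome outside dense bins and across thresholds, and the comparison of fold after a fit on CpG content were chosen only after the results were seen. The design holds 1 group, so no biological difference between groups could be tested. In addition to the fixed lists, 257 groups of at least 10 genes whose symbols share a stem were tested in the same way. The stems overlap the lists. Olfr is the list of 1134 olfactory receptors again, and Hoxa and Hoxb lie within the Hox list. Wnt, Nkx, Sox, Tbx, Fgf and Bmp, among others, share members with the lists, so such calls are not independent of those above. Replicated peaks were found more often in 23 of the 257 stems and less often in 4 (Fisher's exact test, Benjamini-Hochberg adjustment over 257). Of these, Scn, Bmp and Pcdh (more often) and Wdr (less often) did not pass when the occupied state was shifted along the genes (permutation, adjusted p = 0.11, 0.0822, 0.188 and 0.0951). The families of regulators and signals included 16 of 19 Wnt genes, 13 of 14 Nkx genes, 11 of 19 Sox genes, 7 of 13 Tbx genes and 7 of 14 Prdm genes. Several families with members used in neurons were also among the 23. Of 17 synaptotagmins (Syt), many of them calcium sensors of vesicles, 12 were occupied (Fisher adjusted p = 2.46e-07), of 14 calcium channel subunits (Cacna) 9, of 14 serotonin receptors (Htr) 9, and of 15 inward rectifier potassium channels (Kcnj) 8. Of 45 collagens (Col) 12 were occupied (Fisher adjusted p = 0.0170), with 20 in replicate 1 and 14 in replicate 2. None of 330 vomeronasal receptors (Vmn) had a replicated peak at the promoter, and 1 had a peak there in replicate 2, while 13 of 394 zinc finger genes (Zfp) were occupied (3.30%). Genes of such a stem often neighbour each other, and the other stems named here passed that shift as well.

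The 4 pooled peaks with the highest −log10 p did not lead by fold, and the peak with the highest fold, at Pcdh8 (8.64), stood at rank 5 by −log10 p (32.5). The top pair lay on chromosome 17 (39847857 to 39848947 and 39842997 to 39846809), with −log10 p of 173 and 146 and fold of 3.57 and 3.11. The next lay in Cdk8, a gene named outside the rule, on chromosome 5 (146260995 to 146261492), with −log10 p of 84.0 and fold 5.10. Peaks were not screened here for repeated or high-copy sequence. Whether these top peaks arise from such sequence was not tested.

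On the X chromosome, replicate 1 had 7.38 times as many peaks as replicate 2. A difference in depth or threshold that acts alike on all chromosomes is argued against by the ratio on X. It was at least 7.27 times that of the highest autosome at the authors' threshold, at q of 0.01 and at fold 3. At q of 0.01 the autosomes also had 2.83 to 4.22 times as many peaks in replicate 1, and X had 11 peaks in replicate 2. A difference in depth that acts more on X, as where its signal lies nearer the threshold, is not excluded. The densest bins alone are argued against as the source. Outside the 5% of 1-Mb bins with the most peaks of replicate 1 the ratio was still 6.44, against 0.993 or less on autosomes. Those bins held 39.5% of the X peaks of replicate 1, more than the 36.7% of the highest autosome. Peaks of replicate 1 lay in 52.3% of the X bins, against 71.6% to 88.6% on autosomes, so an excess along the whole of X is not shown. Set against its own autosomes, X in replicate 1 was not dense, at 16.3 peaks per Mb against 7.40 to 23.4. X in replicate 2, at 2.21, lay below all of its autosomes (8.82 to 23.2). Whether the difference is an excess in replicate 1 or a shortage in replicate 2 cannot be told from 2 replicates. A larger share of tissue with an inactive X in the pool of replicate 1 may be a source of the difference. It stays open and cannot be told apart from other differences between the pools, since the bodies of 7 genes known to escape inactivation were covered over 0.372% in replicate 1 and 941 other X genes over 1.19% (permutation test, two-sided, p = 0.629), with medians of 0 in both, and the labels give both sexes for both pools.

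Lung regulators carried the mark in the lung, where many of them are used in some cells. Their occupied promoters had a fold of 4.30 ± 0.905 (SD, n = 21 genes), below the 6.01 ± 1.06 (SD, n = 35 genes) of neural factors (permutation test, two-sided, p = 1e-05, the smallest possible), and the same order held in replicate 1 (p = 1e-05) and replicate 2 (p = 0.00013). The windows were also less fully covered, over 52.6% against 91.3% (permutation test, two-sided, p = 1e-05). The highest fold in a window can rise with the amount of peak sequence there, and fold and covered share were not separated. The CpG content of the promoters does not account for the excess of occupied lung epithelial factors (permutation test against matched random lists, adjusted p = 0.000575), nor for the lower fold, which differed by -1.62 after a linear fit on CpG content. A candidate explanation is that the mark lies on part of the cells of this mixed tissue and is absent where the factor is used. The lower fold is what this hypothesis needs. The neural list had the highest median fold of all lists (6.22), so every other list lay below it. Both lung lists also had lower medians than the Hox genes, the neuronal effector genes and the factors of gut and heart. The WNT, FGF, BMP and hedgehog list (4.77) lay above both lung lists too. A low fold was still not particular to lung regulators. Endothelial, alveolar, fibroblast and striated muscle markers and keratins had lower medians than both lung lists. These medians were not tested against each other. Weak marking in all cells would give the same lower fold.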
